A study of Mus musculus with 20 samples.

How the data were processed

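RNA was measured in 20 sorted cell libraries from 6 mice. Per the labels, reporter-positive NE cells and EpCAM-positive, reporter-negative epithelial cells were sorted from mice carrying a tamoxifen-inducible Cre recombinase under Ascl1 control and a tdTomato reporter, and libraries were made with a full-length cDNA kit (SMART-Seq v4) and Nextera XT. Mice 1 to 3 gave lung cells and mice 4 to 6 tracheal and laryngeal cells, and trachea epithelium came from mice 4 and 5. Same-numbered libraries therefore shared a mouse among the lung groups and among the tracheal and laryngeal groups, per the labels, and not between these sets.

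The deposited table holds 42458 entries in 20 sample columns, and no column was left unused. Per the submitters' processing notes, reads were checked with FastQC, trimmed with cutadapt and Trim Galore and quantified with RSEM 1.3.3 on mm10, which is the mouse build GRCm38. The aligner and the gene annotation are not given in the sources used here. As deposited, the score of each gene is its TPM (transcript abundance scaled to a fixed total) rounded to a whole number: 100% of the values are whole, and the columns sum to between 996968 and 999650. TPM does not keep the number of reads, so depth is unknown and no counting interval can be given. Rounding hides differences below 1 TPM. Of 16 genes that every cell uses, only Polr2a was at 0, in 1 library.

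Numbered copies of a symbol were summed (2341 entries merged), which left 40117 genes. Genes at 1 TPM or more in at least 2 samples were tested, 19239 in all. Positions are those of the GRCm38 annotation (patch 6), in which 18348 of the tested symbols were found. No pair of the 190 pairs of columns was identical, and the correlation of log2(TPM + 1) within groups ran from 0.896 to 0.975, so every library was counted as a replicate.

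Differences were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean for each of the 7 groups, all 20 samples sharing 1 estimate of the spread, a trend of the variance with level, and Benjamini-Hochberg adjustment over the genes of a comparison at a threshold of 0.05. There were 12 comparisons: NE cells against epithelium in lung, lower trachea, upper trachea and larynx, the 6 pairs of NE groups, larynx against lung epithelium, and the difference between larynx and lung in the contrast of NE cells with epithelium. Lower and upper trachea NE cells were set against the same 2 trachea epithelium libraries, so these comparisons share chance values, and no overlap between them is given.

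The median gene lay above or below 0 on the log2 scale by 0.77, 0.76, 0.54 and 0.61 in lung, lower trachea, upper trachea and larynx NE cells against epithelium. It was at 0.47, 0.53 and 0.33 for larynx, lower trachea and upper trachea against lung NE cells, at -0.20 for upper against lower trachea, at -0.02 and 0.12 for larynx against lower and upper trachea NE cells, at 0.63 for larynx against lung epithelium and at -0.23 for the difference of contrasts. Printed log2 differences are relative to these shifts. The adjusted p beside them tests the unshifted difference. A gene was called higher or lower only where TPM as deposited and median-of-ratios scaling (each library divided by its median ratio to the gene-wise geometric mean) both passed the threshold in 1 direction. This rule was chosen after the data were examined.

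Camera compared 32 fixed gene lists with all other tested genes in each comparison at a preset correlation of 0.01, with adjustment over the 384 tests. It was run again with the correlation estimated within each list, which left 12 of 140 calls; each call's value under it stands beside it. The lists named 514 genes, of which 420 were tested. The gene lists, the limma and camera tests and the rule for named genes were fixed before the data were examined. So were the alternatives and the tests of possible causes, except those described as later. A list of 32 interferon-stimulated genes was written after.

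The genes named were chosen by rule. In each comparison of NE cells with epithelium they were the 10 largest and 6 smallest log2 differences among called genes with a mean of 10 TPM or more in the higher group and no overlap between the groups' samples. In the other comparisons they were the 8 largest and 8 smallest, for the difference of contrasts with a mean of 10 TPM in any of its 4 groups and without the overlap condition. Up to 4 members of each list with the smallest p were added, as were Ascl1, Calca, Chga, Epcam, Piezo2, Asic1, Slc17a9, Trpm5, Scn9a, Nkx2-1 and Xist, and genes of a count of 5 or fewer. Predicted, clone-named and mitochondrial genes were passed over. Markers of other cell types, housekeeping genes and reporter entries are given as levels, and Isg15, Rsad2 and Oasl2 were chosen after their values were seen.

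Whether same-numbered libraries deviate together was checked by correlating their deviations from the group means. In mice 4 to 6 the mean r was 0.10 over 26 same-mouse pairs (from -0.06 to 0.33, 18 of them above 0) and -0.05 over different mice. In mice 1 to 3 it was 0.09 over 3 pairs and -0.05 over different mice. The pairing comes from the labels, and a fit with the mouse as a block was run as an alternative.

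The alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, the mouse as a block, each library left out in turn, only the groups compared in the fit, median-of-ratios scaling, quantile normalization, array weights and the estimated correlation. Alternatives added after the data were examined left copies of a symbol unsummed, left upper trachea NE 3 out of every fit, and kept genes called under both scalings.

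The test was checked on simulated values for 19239 genes with the real means and spreads. For larynx NE against larynx epithelium it called 16 of 100 genes changed by 1 on the log2 scale and 65 of 100 changed by 2, each in the right direction, with 8 unchanged genes among 89 calls. For upper against lower trachea NE cells the numbers were 10, 74 and 2 of 86. No other gene was changed, against 8034 real calls in larynx, so the larynx shares need not hold there. A shift of 1 in the 26 exocytosis genes gave a camera adjusted p = 1.1e-21, and 0 of 31 other lists was called. Genes varied independently, so camera is untested where members of a list vary together.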

Results

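RNA was sequenced from neuroendocrine (NE) cells and other epithelial cells sorted from 4 levels of the mouse airway: lung, lower trachea, upper trachea and larynx. NE cells are rare sensory cells of the airway lining that store and secrete peptides and amines. They were sorted by a tdTomato reporter that tamoxifen switches on in cells expressing Ascl1, and the comparison cells were sorted as EpCAM-positive and tdTomato-negative. The 20 libraries formed 7 groups: lung NE (n = 3), lower trachea NE (n = 3), upper trachea NE (n = 3), larynx NE (n = 3), lung epithelium (n = 3), trachea epithelium (n = 2) and larynx epithelium (n = 3). Each library of a group came from a separate mouse. Mice 1 to 3 gave the lung cells and mice 4 to 6 the tracheal and laryngeal cells, so tissue and set of mice cannot be told apart between lung and the upper airway.

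The values were TPM rounded to whole numbers, so sequencing depth was unknown. Between 12970 and 15436 genes stood at 1 TPM or more in the NE libraries, and between 10670 and 13995 in the epithelial libraries. Scgb1a1, the secretoglobin of club cells, held 38.9 to 53.7% of all TPM in lung epithelium and at most 8.02% in any other library. TPM divides a fixed total, and the median gene was 0.77 higher on the log2 scale in lung NE cells than in lung epithelium. Each log2 difference is therefore given relative to the median gene of its comparison, with its SE, on the log2(TPM + 1) scale, which understates the change of low genes. Genes are called higher or lower where limma's adjusted p was under 0.05 both on TPM as deposited and after median-of-ratios scaling. The adjusted p printed is that on TPM as deposited. It tests the difference before the median gene is subtracted, so the value tested can differ in sign from a printed difference near 0. For each named gene so called between a pair of groups, every library of the higher group lay above every library of the lower. Chance gives such a separation at a share of 0.1 with 3 against 3, and at a larger share with 3 against 2. It was a condition for the genes named by size of difference, so it lends them no support. Levels are mean ± SD over the libraries of a group (n = 3, and n = 2 for trachea epithelium). Where a library of a group was listed at 0, the libraries' values are given in the order of the mice. Between a pair of groups no fold is given against a group at 0 throughout. Larynx minus lung differences of contrasts are printed even where a group is at 0, and their size then depends on the pseudocount. For each fixed gene list the number of members called is followed by the number that was significant on TPM as deposited adjusted over the list alone, and by camera's adjusted p with the lowest and highest adjusted p over the alternatives as its range. A 0 was not read as absence, since Polr2a, a subunit of RNA polymerase II, was itself at 0 in lung epithelium 3.

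**Figure D1:**
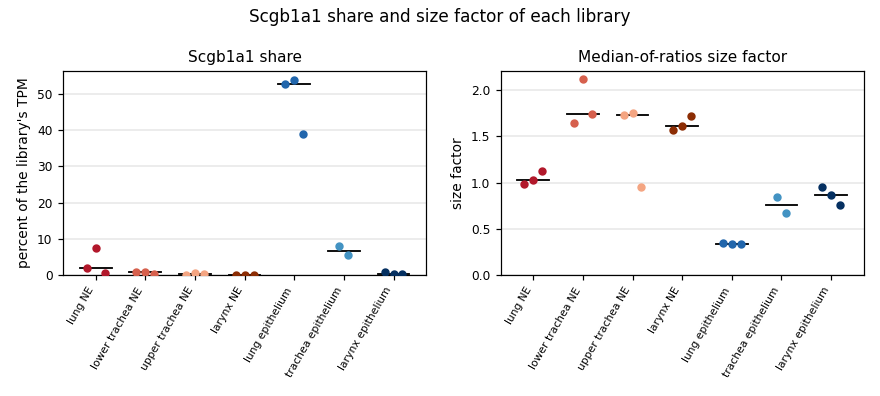
Share of all TPM held by Scgb1a1 (percent) and median-of-ratios size factor, for each of the 20 libraries, with groups along the horizontal axis, points for libraries and a black line at the group median. Lung epithelium sits at 38.9 to 53.7% for Scgb1a1 with size factors of 0.33 to 0.35, and the NE libraries of trachea and larynx reach size factors of 0.95 to 2.12.

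Ascl1, the transcription factor behind the reporter (chromosome 10, 87490819 to 87493660), stood at 28.7 ± 6.43 TPM in lung NE, 197 ± 31.8 TPM in lower trachea NE, 192 ± 59.6 TPM in upper trachea NE and 142 ± 22.8 TPM in larynx NE, and was listed at 0 in all epithelial libraries; it belongs to the sort itself. Calca, which encodes calcitonin gene-related peptide (chromosome 7, 114625981 to 114636910), stood at 3959 ± 1525 TPM, 4890 ± 1909 TPM, 4120.3 ± 199 TPM and 1775 ± 135 TPM in the same order, against 16.7 ± 9.07 TPM in lung, 2 ± 1.41 TPM in trachea and 2.67 ± 0.580 TPM in larynx epithelium. Chga, the granule protein chromogranin A (chromosome 12, 102554941 to 102565027), was at 27 ± 12.5 TPM in lung NE, 1229 ± 115 TPM in lower trachea NE, 843 ± 589 TPM in upper trachea NE and 839.7 ± 93.5 TPM in larynx NE, and at 0 or 1 TPM in every epithelial library. Epcam, the surface antigen of the epithelial sort (chromosome 17, 87635979 to 87651127), was at 2107 ± 449 TPM, 1444 ± 81.3 TPM, 1082 ± 452 TPM and 1241 ± 82.8 TPM in the NE groups, and at 150 ± 15.4 TPM, 246 ± 11.3 TPM and 385 ± 85.0 TPM in lung, trachea and larynx epithelium. Scn9a, the sodium channel Nav1.7 (chromosome 2, 66480080 to 66635114), was at 2.67 ± 2.08 TPM in lung NE, 106 ± 12.9 TPM in lower trachea NE, 84.7 ± 31.3 TPM in upper trachea NE and 109 ± 14.2 TPM in larynx NE, and was listed at 0 in all epithelial libraries.

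Piezo2, a mechanically gated channel (chromosome 18, 63010213 to 63387716), was at 19.3 ± 6.03 TPM in lung NE, 10 ± 5.57 TPM in lower trachea NE and 7, 2 and 0 TPM in upper trachea NE, and was listed at 0 in all larynx NE and epithelial libraries. Slc17a9, the vesicular ATP transporter (chromosome 2, 180724576 to 180742280), stood at 0, 1 and 1 TPM in lung NE, 19.7 ± 2.08 TPM in lower trachea NE, 14.7 ± 10.5 TPM in upper trachea NE and 16.3 ± 1.53 TPM in larynx NE, and at 4.50 ± 0.710 TPM in trachea and 3.33 ± 0.580 TPM in larynx epithelium, with 0 in lung epithelium. Trpm5, a cation channel of taste cells (chromosome 7, 143071529 to 143094642), was at 9 ± 9.85 TPM in lower trachea NE, 7 ± 2.65 TPM in upper trachea NE, 8.33 ± 2.08 TPM in larynx NE, 2 ± 1.41 TPM in trachea epithelium and 1.67 ± 0.580 TPM in larynx epithelium, and at 0 in both lung groups. Nkx2-1, the lung and thyroid transcription factor (chromosome 12, 56531935 to 56536908), was at 39.7 ± 9.71 TPM, 30.7 ± 9.87 TPM, 20.7 ± 4.93 TPM and 17 ± 5.20 TPM in NE cells from lung to larynx, and at 2.67 ± 0.580 TPM, 18 ± 11.3 TPM and 5.33 ± 2.31 TPM in the 3 epithelia. Asic1, an acid-sensing channel (chromosome 15, 99670197 to 99701130), was listed at 0 in all 20 libraries. Xist, the RNA of the inactive X chromosome (chromosome X, 103460373 to 103483233), was at 0 or 1 TPM in all libraries of mice 3 and 4, and between 4 and 83 TPM in all others.

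Upper trachea NE 3 stood apart from the other libraries. Actb was at 151 TPM there and at 642 TPM or more elsewhere, Gapdh at 29 against 93 TPM or more, and the nuclear RNA Malat1 at 36760 against at most 21876 TPM. Chga was at 163 TPM in it and at 1199 and 1166 TPM in the other upper trachea NE libraries. A reporter entry named Ai9 was at 551 TPM in this library, 1437 to 2949 TPM in the other NE libraries and 20 to 55 TPM in the epithelial ones.

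Lung NE cells against lung epithelium showed which transcripts mark NE cells of the lung. Calca differed by 7.13 ± 0.39, adjusted p = 6.5e-10, and Resp18, an endocrine secretory protein, by 6.56 ± 0.56, adjusted p = 7.2e-08, from 121 ± 144 TPM in epithelium to 12416 ± 2703 TPM in NE cells. Spp1 (osteopontin) was higher by 8.35 ± 1.23, adjusted p = 2.1e-05, at 7117 ± 1914 TPM in NE cells, and Iapp (amylin) by 7.83 ± 0.93, adjusted p = 2.4e-06, at 3225 ± 209.9 TPM. Among the list of NE identity genes, 15 of 16 tested members were higher (16 adjusted over the list alone), among them Scg5 (6.89 ± 0.49) and Bex2 (4.77 ± 0.27). Camera gave 1.5e-12 for an upward shift (range 1.7e-17 to adjusted p = 0.037 with an estimated correlation). For the exocytosis genes, 19 of 26 tested members were higher (21 adjusted over the list alone), with Snap25, a protein of vesicle fusion, at 341 ± 29.1 TPM and Ptprn at 148 ± 48.5 TPM. Camera gave 4.7e-07 for an upward shift (range 1.7e-12 to adjusted p = 0.19 with an estimated correlation). Of the peptide hormone genes, 11 of 22 tested members were higher and 1 was lower (12 and 1 adjusted over the list alone), with Scg2 at 587 ± 48.2 TPM and Cartpt at 417 ± 109 TPM in NE cells. Camera gave 0.0047 for an upward shift (range 1.7e-05 to 0.35, adjusted p = 0.27 with an estimated correlation, and 0.056 with a pseudocount of 0.1 and 0.35 with only the groups compared fitted).

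Lung epithelium was higher in transcripts of the other lung cell types. Scgb1a1 stood at 483972 ± 82916 TPM there and 32671 ± 36231 TPM in NE cells, a difference of -5.36 ± 0.96, adjusted p = 0.00091 (adjusted p = 0.16 with quantile normalization, range 9.7e-05 to 0.16 over the alternatives). Among the club cell genes, 6 of 9 tested members were lower (6 adjusted over the list alone) in NE cells. Camera gave 7.8e-08 for a downward shift (range 9.6e-09 to adjusted p = 0.12 with an estimated correlation). Of the alveolar type 2 genes, 8 of 10 tested members were lower (8 adjusted over the list alone), with surfactant protein C, Sftpc, at 1192 ± 1421 TPM in NE cells and 28089 ± 15067 TPM in epithelium. Camera gave 7.4e-09 for a downward shift (range 5.9e-10 to adjusted p = 0.037 with an estimated correlation). For the ciliated cell genes, 7 of 10 tested members were lower (8 adjusted over the list alone), with Dynlrb2, a dynein light chain, lower (-7.33 ± 0.84, adjusted p = 1.2e-05). Camera gave 7.1e-12 for a downward shift (range 2.2e-14 to adjusted p = 0.12 with an estimated correlation). Hes1, a target of Notch signalling, was lower in NE cells (-2.67 ± 0.36, adjusted p = 0.00044). Single markers of stromal and immune cells went different ways: Dcn was at 141 ± 79.7 TPM in NE cells against 3.33 ± 1.53 TPM, while Lum and Col1a2 were at 0 in both, and Tyrobp was at 20 ± 11.4 TPM against 1, 3 and 0 TPM, C1qb at 8, 1 and 0 against 0, 3 and 0 TPM, and Cd74 at 255, 62 and 83 against 623, 385 and 490 TPM. Malat1 stood at 3816 to 9932 TPM in NE cells and 2152 to 4083 TPM in epithelium, and Gapdh at 1025 to 1816 and 256 to 647 TPM. With TPM as deposited limma called 8311 of 19239 genes higher and 943 lower in lung NE cells, 89.8% of the calls higher. Under median-of-ratios scaling 2982 were higher and 2482 lower, 54.6% higher, and 2946 and 943 were called under both. Between these scalings 120 genes were called in opposite directions.

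**Figure D2:**
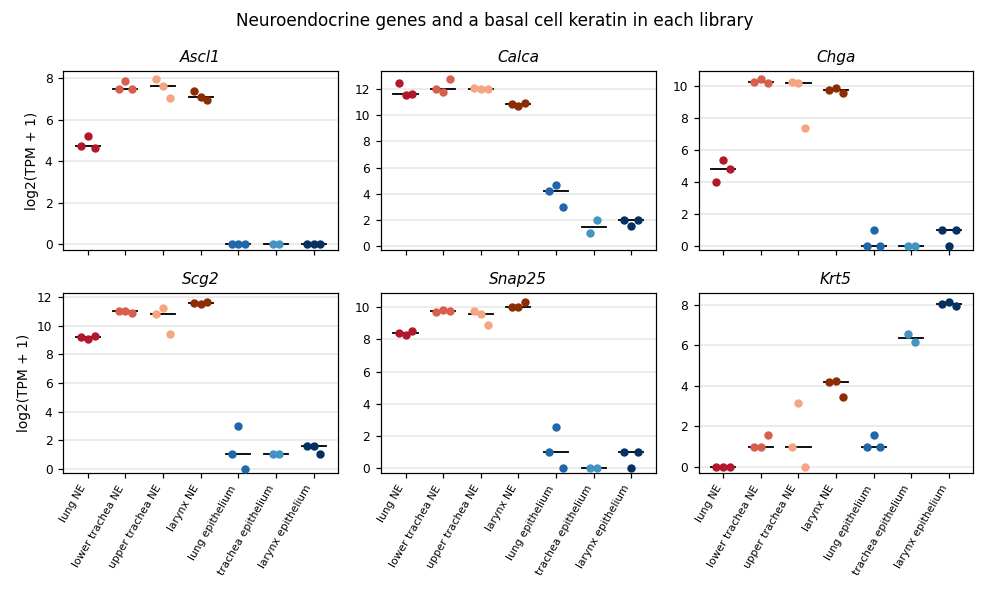
Levels of Ascl1, Calca, Chga, Scg2, Snap25 and Krt5 in log2(TPM + 1) for each library, with the 4 NE groups first and the 3 epithelia after them, points for libraries and a black line at the group median. Calca lies at 1631 TPM or more in all NE libraries and at 25 TPM or less in all epithelial libraries, while Krt5 is highest in larynx epithelium.

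Lower trachea NE cells were set against trachea epithelium. The chemokine Cxcl13 stood at 9009 ± 2813 TPM in NE cells and 3.50 ± 0.710 TPM in epithelium (10.16 ± 0.80, adjusted p = 4.8e-08), and Ccn3, a secreted matrix protein, at 8568 ± 2859 TPM and 9.50 ± 0.710 TPM (8.86 ± 0.56, adjusted p = 3.8e-09). Calca differed by 9.93 ± 0.43, adjusted p = 8.4e-11 and Scg2 by 9.22 ± 0.60, adjusted p = 5.3e-09. Nerve growth factor, Ngf, was at 796 ± 119 TPM, Snap25 at 884 ± 32.0 TPM and the prohormone convertase Pcsk1 at 551 ± 227 TPM, each listed at 0 in epithelium (limma adjusted p at most 2e-09). Of the NE identity genes, 16 of 16 tested members were higher (16 adjusted over the list alone). Camera gave 1.3e-18 for an upward shift (range 5.1e-29 to adjusted p = 0.022 with an estimated correlation). Among the exocytosis genes, 21 of 26 tested members were higher (23 adjusted over the list alone). Camera gave 2.8e-11 for an upward shift (range 1.1e-17 to adjusted p = 0.091 with an estimated correlation). For the sodium and calcium channel genes, 12 of 20 tested members were higher (14 adjusted over the list alone), with Scn3a at 36.3 ± 10.5 TPM and Cacna2d1 higher by 4.56 ± 0.43, adjusted p = 1.4e-07. Camera gave 0.00049 for an upward shift (range 8.4e-07 to adjusted p = 0.3 with an estimated correlation, and 0.065 with only the groups compared fitted). Elavl4, an RNA-binding protein of neurons that NE cells also make, was at 105 ± 6.11 TPM and listed at 0 in epithelium. The nuclear RNA Malat1 was at 11074 to 17039 TPM in NE cells and 6403 and 2705 TPM in epithelium.

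Trachea epithelium was higher in basal, gland and club cell transcripts. Of the basal cell genes, 8 of 8 tested members were lower (8 adjusted over the list alone) in NE cells, with the basal keratin Krt5 lower (-5.93 ± 0.59, adjusted p = 6.8e-06), from 82 ± 15.6 TPM to 1.33 ± 0.580 TPM. Camera gave 1.3e-10 for a downward shift (range 6.3e-11 to adjusted p = 0.037 with an estimated correlation). Among the gland and goblet cell genes, 10 of 10 tested members were lower (10 adjusted over the list alone), with the mucosal peptide Tff2 lower (-7.44 ± 0.90, adjusted p = 3.1e-05) and the secreted protein Dcpp3 (-8.62 ± 0.56, adjusted p = 3.7e-08). Camera gave 6.6e-14 for a downward shift (range 2e-17 to adjusted p = 0.023 with an estimated correlation). The Dcpp genes are near-identical, so their shares of reads are uncertain. For the club cell genes, 8 of 9 tested members were lower (8 adjusted over the list alone), with Scgb3a2 at 2275 ± 1512 TPM in NE cells and 33529 ± 1508 TPM in epithelium. Camera gave 3.7e-08 for a downward shift (range 9.6e-09 to adjusted p = 0.12 with an estimated correlation). Hes1 was lower (-4.85 ± 0.40, adjusted p = 1.4e-06), while Hes6, which opposes it, was higher by 3.15 ± 0.37, adjusted p = 8.6e-07. Of the immediate early and heat shock genes, 7 of 18 tested members were lower (7 adjusted over the list alone), with Hspa1b at 36 ± 9.17 TPM against 420 ± 209 TPM. Camera gave 2e-05 for a downward shift (range 3.6e-08 to adjusted p = 0.45 with an estimated correlation). The stromal transcript Dcn was at 47.7 ± 11 TPM in NE cells and 298 ± 26.2 TPM in epithelium, and the muscle transcript Acta2 was at 1, 157 and 52 TPM in lower trachea NE and 0 in trachea epithelium. By limma on TPM as deposited, the calls were 7427 genes higher and 1224 lower, 85.9% higher. Under median-of-ratios scaling 1905 were higher and 2119 lower, 47.3% higher, and 1905 and 1181 were called under both. The count of 8651 rested partly on the epithelial libraries: without trachea epithelium 2 it was 5195, with the lone library assumed to vary like the other groups.

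Upper trachea NE cells were set against the same trachea epithelium. Cxcl13 stood at 10848 ± 3811 TPM in NE cells (10.65 ± 0.80, adjusted p = 4.4e-08), Calca differed by 9.97 ± 0.43, adjusted p = 1.1e-10, and Pkib, an inhibitor of protein kinase A, by 8.64 ± 0.48, adjusted p = 1.4e-09. Among the NE identity genes, 16 of 16 tested members were higher (16 adjusted over the list alone), with Scg5 at 1890 ± 505 TPM and Ddc, the decarboxylase of dopamine and serotonin synthesis, higher by 8.12 ± 0.45, adjusted p = 1.3e-09. Camera gave 4.2e-20 for an upward shift (range 1.2e-27 to adjusted p = 0.022 with an estimated correlation). For the exocytosis genes, 20 of 26 tested members were higher (23 adjusted over the list alone). Camera gave 1.1e-11 for an upward shift (range 2.2e-16 to adjusted p = 0.09 with an estimated correlation). Of the sodium and calcium channel genes, 12 of 20 tested members were higher (14 adjusted over the list alone). Camera gave 0.00015 for an upward shift (range 8.4e-07 to adjusted p = 0.29 with an estimated correlation). Among the gland and goblet cell genes, 10 of 10 tested members were lower (10 adjusted over the list alone). Camera gave 2.7e-11 for a downward shift (range 1.1e-14 to adjusted p = 0.037 with an estimated correlation). Gp2, a surface glycoprotein, was lower (-6.79 ± 0.72, adjusted p = 9e-06), at 6.67 ± 1.53 TPM against 576 ± 43.1 TPM. Krt5 stood at 1, 8 and 0 TPM and Krt17 at 5 ± 4 TPM. For the basal cell genes, 8 of 8 tested members were lower (8 adjusted over the list alone). Camera gave 4.9e-11 for a downward shift (range 2.5e-12 to adjusted p = 0.037 with an estimated correlation). In upper trachea NE Malat1 was at 7862 to 36760 TPM against the same epithelium. Upper trachea NE 2 also held immune transcripts, with Cd74 at 98 and C1qb at 14 TPM against 0 or 1 TPM in the other libraries of its group. On TPM as deposited limma called 5251 genes higher and 1290 lower, 80.3% higher. Under median-of-ratios scaling 1951 were higher and 2195 lower, 47.1% higher, and 1951 and 1268 were called under both. The count of 6541 was 4237 without trachea epithelium 2, and 8818 without upper trachea NE 3, which shared 6107 genes with it.

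Larynx NE cells were set against larynx epithelium of the same mice. Scg2 was at 3139 ± 165 TPM against 1.67 ± 0.580 TPM (9.62 ± 0.54, adjusted p = 6.9e-10), Ccn3 at 9180.3 ± 1665 TPM against 8 ± 2 TPM (9.40 ± 0.50, adjusted p = 3.9e-10), and Cxcl13 at 6425 ± 1354 TPM against 5.33 ± 1.15 TPM (9.37 ± 0.72, adjusted p = 2.5e-08). Of the NE identity genes, 16 of 16 tested members were higher (16 adjusted over the list alone). Camera gave 2.8e-18 for an upward shift (range 1.6e-25 to adjusted p = 0.022 with an estimated correlation). Among the exocytosis genes, 22 of 26 tested members were higher (24 adjusted over the list alone). Camera gave 3.1e-12 for an upward shift (range 1.1e-16 to adjusted p = 0.085 with an estimated correlation). For the sodium and calcium channel genes, 16 of 20 tested members were higher (17 adjusted over the list alone), with Scn3a at 46.3 ± 10.1 TPM and Cacna2d1 higher by 5.35 ± 0.38, adjusted p = 7.6e-09. Camera gave 6.6e-07 for an upward shift (range 1.4e-09 to adjusted p = 0.15 with an estimated correlation). Gad1, which makes GABA, was at 48 ± 5.20 TPM, Tph1, which makes serotonin, at 51.3 ± 30.7 TPM, the sour taste channel Otop1 at 4, 13 and 7 TPM and Pkd2l1 at 16.7 ± 7.37 TPM, all listed at 0 in larynx epithelium (adjusted p at most 2.5e-06). Gnat3, the taste G protein gustducin, was at 1797 ± 561 TPM in NE cells and 135 ± 26.1 TPM in epithelium (3.08 ± 0.75, adjusted p = 0.00097). Of the tuft and taste cell genes, 6 of 17 tested members were higher (11 adjusted over the list alone). Camera gave 0.28. Malat1 stood at 13040 to 21876 TPM in larynx NE and 2738 to 5404 TPM in larynx epithelium.

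Larynx epithelium was higher in squamous, gland, basal and dividing cell transcripts. Among the squamous and hillock cell genes, 13 of 14 tested members were lower (13 adjusted over the list alone) in NE cells, with Krt4 lower (-6.46 ± 0.68, adjusted p = 5.1e-06) and Cnfn, a protein of the cornified layer (-8.73 ± 0.52, adjusted p = 7.4e-09). Camera gave 6.3e-18 for a downward shift (range 2.4e-19 to adjusted p = 0.022 with an estimated correlation). For the gland and goblet cell genes, 10 of 10 tested members were lower (10 adjusted over the list alone), with Tff2 at 5 ± 1.73 TPM against 2122 ± 1166 TPM. Camera gave 1.4e-14 for a downward shift (range 1.5e-15 to adjusted p = 0.023 with an estimated correlation). Sbpl fell by 9.49 ± 0.37 (adjusted p = 7.7e-11), and Lipf, gastric lipase, from 8066 ± 3554 TPM to 23.7 ± 4.04 TPM in NE cells (-8.85 ± 1.3, adjusted p = 0.00011). Of the basal cell genes, 7 of 8 tested members were lower (7 adjusted over the list alone), with Krt15 lower (-5.14 ± 0.70, adjusted p = 8.8e-05). Camera gave 1.3e-08 for a downward shift (range 4.8e-09 to adjusted p = 0.059 with an estimated correlation). Among the cell cycle genes, 12 of 16 tested members were lower (12 adjusted over the list alone), with the kinase Cdk1 at 2.33 ± 1.53 TPM against 23.3 ± 5.51 TPM. Camera gave 1.3e-10 for a downward shift (range 5.5e-11 to adjusted p = 0.12 with an estimated correlation). The stromal transcript Dcn was at 202, 141 and 44 TPM in larynx NE and 167, 118 and 74 TPM in larynx epithelium. With TPM as deposited limma called 6544 genes higher and 1490 lower, 81.5% higher. Under median-of-ratios scaling 2697 were higher and 2442 lower, 52.5% higher, and 2697 and 1455 were called under both.

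Genes called in NE cells of lung, lower trachea and larynx against their own epithelia overlapped. Under both scalings 744 genes were higher in all 3 comparisons, where independent lists of these sizes drawn from all 19239 genes would share 40.9. A further 272 were lower, where 4.4 would be shared. Genes too low to be called anywhere count among the 19239, so the expected numbers lie below those for genes that could be called. The higher genes included Ascl1, which belongs to the sort itself, and Calca, Scg2, Snap25 and Epcam, and the lower ones Hes1. The comparisons share no library, but lower trachea and larynx share mice. The expected numbers do not hold for TPM as deposited. There 8311, 7427 and 6544 genes were higher in lung, lower trachea and larynx NE cells, and independent lists of such length would share more. On TPM as deposited the count of genes higher in NE cells of lung, lower trachea and larynx alike was 3583, and 2374 without trachea epithelium 2; the count of genes lower in NE cells of lung, lower trachea and larynx alike was 273, and 180 without trachea epithelium 1.

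Larynx NE cells against lung NE cells asked how NE cells differ with airway level. Larynx NE cells held more transcripts of taste transduction: Gnat3 stood at 1797 ± 561 TPM, its partner Gng13 at 637 ± 141 TPM and Rgs13 at 85.3 ± 22.5 TPM, each listed at 0 in lung NE cells (adjusted p at most 2.1e-06). For the tuft and taste cell genes, 13 of 17 tested members were higher (14 adjusted over the list alone). Camera gave 2e-05 for an upward shift (range 7e-07 to adjusted p = 0.3 with an estimated correlation). Scn9a was higher by 4.58 ± 0.34, adjusted p = 2.7e-08, Scn3a by 2.68 ± 0.32, adjusted p = 2.2e-06 and Cacna2d1 by 2.47 ± 0.38, adjusted p = 2.2e-05. Of the sodium and calcium channel genes, 11 of 20 tested members were higher and 2 were lower (13 and 2 adjusted over the list alone). Camera gave 0.0081 for an upward shift (range 0.0016 to adjusted p = 0.45 with an estimated correlation, and 0.11 with only the groups compared fitted). Among the positional transcription factor genes, 19 of 31 tested members were higher and 1 was lower (22 and 2 adjusted over the list alone), with Isl1 at 102 ± 19.3 TPM and Eya1 at 43.3 ± 1.53 TPM, both at 0 in lung, and Hoxb5 higher by 3.73 ± 0.37, adjusted p = 4.2e-07. Camera gave 1.7e-05 for an upward shift (range 4.3e-07 to adjusted p = 0.29 with an estimated correlation). Chga was higher by 4.54 ± 0.58, adjusted p = 6.9e-06, Ddc by 4.34 ± 0.40, adjusted p = 2.5e-07, the ATP channel Panx1 at 43.3 ± 7.37 TPM against 3, 0 and 4 TPM, and the adenosine receptor Adora2b by 3.95 ± 0.50, adjusted p = 5.6e-06. Hepacam2 was at 922 ± 119.6 TPM and 0 in lung. Of the immediate early and heat shock genes, 5 of 18 tested members were higher (7 adjusted over the list alone), with Fos higher by 2.39 ± 0.60, adjusted p = 0.0014 and Dnajb1, a heat shock protein, by 1.95 ± 0.35, adjusted p = 5.5e-05. Camera gave an adjusted p of 0.23 for an upward shift of the list (range 0.031 with quantile normalization to 0.84). Signs of RNA quality differed between larynx and lung NE libraries as well. Malat1 stood at 13040 to 21876 TPM in larynx NE, 11074 to 17039 TPM in lower trachea NE, 7862 to 36760 TPM in upper trachea NE and 3816 to 9932 TPM in lung NE. Gapdh was at 156 to 221, 188 to 253, 29 to 261 and 1025 to 1816 TPM in the same order, and ribosomal protein genes held 3.3 to 4.5, 2.5 to 4.3, 3.7 to 4.7 and 7.6 to 9.7% of TPM.

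Other genes were higher in lung NE cells. Spp1 was lower in larynx (-10.03 ± 1.23, adjusted p = 2e-05), and Igf2, insulin-like growth factor 2, stood at 409.7 ± 193 TPM in lung NE and 0 in larynx NE (adjusted p = 2.4e-10). Cartpt was at 417 ± 109 TPM and 1, 0 and 0 TPM, galanin, Gal, at 265 ± 162 TPM and 0, 3 and 0 TPM, and Vgf was lower in larynx (-4.63 ± 0.36, adjusted p = 3.8e-07). For the peptide hormone genes, 2 of 22 tested members were higher and 7 were lower (3 and 7 adjusted over the list alone). Camera gave 7e-06 for a downward shift (range 9.6e-07 to adjusted p = 0.085 with an estimated correlation). The chemokine Ccl2 stood at 558 ± 285 TPM against 4, 0 and 1 TPM, and Ccl5 at 340.3 ± 226 TPM against 0. Piezo2 was at 19.3 ± 6.03 TPM and the oxygen-regulated subunit Cox4i2 at 11.3 ± 3.51 TPM in lung NE, both at 0 in larynx NE (adjusted p at most 1.3e-05). Of the antigen presentation genes, 5 of 14 tested members were lower (6 adjusted over the list alone), with B2m lower (-2.72 ± 0.35, adjusted p = 0.00011). Camera gave 0.0015 for a downward shift (range 0.00016 to adjusted p = 0.44 with an estimated correlation). Among the immune cell markers, 2 of 9 tested members were lower (2 adjusted over the list alone). Camera gave 0.00046 for a downward shift (range 2e-04 to adjusted p = 0.16 with an estimated correlation). Cd74 was at 255, 62 and 83 TPM in lung NE and 0, 8 and 107 TPM in larynx NE. Sftpc of alveolar cells was at 1192 ± 1421 TPM in lung NE and Scgb1a1 at 32671 ± 36231 TPM. By limma on TPM as deposited, the calls were 5780 genes higher in larynx and 1504 lower, 79.4% higher. Under median-of-ratios scaling 3301 were higher and 2239 lower, 59.6% higher, and 3301 and 1467 were called under both.

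**Figure D3:**
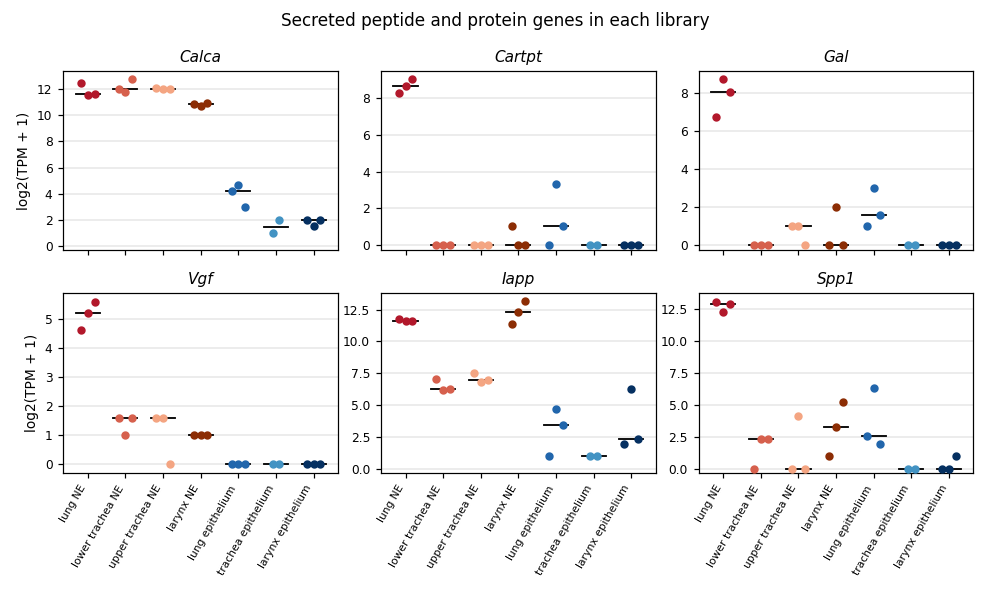
Levels of Calca, Cartpt, Gal, Vgf, Iapp and Spp1 in log2(TPM + 1) for each library, with the 4 NE groups first and the 3 epithelia after them, points for libraries and a black line at the group median. Cartpt lies at 313 to 530 TPM in lung NE and at 0 or 1 TPM in the NE cells of trachea and larynx, while Iapp reaches 2637 TPM or more in larynx NE.

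Lower trachea NE cells were next compared with lung NE cells. Serpinb12, a serine protease inhibitor, was at 1079.7 ± 299 TPM against 1, 0 and 0 TPM (9.18 ± 0.38, adjusted p = 7.2e-11), Cxcl13 was higher by 8.91 ± 0.72, adjusted p = 1.1e-07, and the potassium channel Kcnj1 was at 185 ± 62.4 TPM and 0 in lung (adjusted p = 2.1e-09). Scn9a was higher by 4.49 ± 0.34, adjusted p = 3.3e-08, Chga by 5.03 ± 0.58, adjusted p = 2.8e-06 and Ascl1 by 2.22 ± 0.24, adjusted p = 4.4e-07. For the NE identity genes, 9 of 16 tested members were higher and 1 was lower (11 and 1 adjusted over the list alone). Camera gave 0.0034 for an upward shift (range 2.7e-05 to adjusted p = 0.36 with an estimated correlation). Of the positional transcription factor genes, 13 of 31 tested members were higher (20 adjusted over the list alone). Camera gave 0.0016 for an upward shift (range 0.00012 to adjusted p = 0.44 with an estimated correlation). Among the tuft and taste cell genes, 8 of 17 tested members were higher (12 adjusted over the list alone). Camera gave 0.0062 for an upward shift (range 5.2e-05 to adjusted p = 0.53 with an estimated correlation, and 0.068 with array weights). Spp1 stood at 0, 4 and 4 TPM, Sprr1a, of the cornified envelope, at 17 ± 17.1 TPM against 6670 ± 2948 TPM in lung (-9.49 ± 0.84, adjusted p = 9.7e-07), and Cartpt, Gal and Ccl2 were listed at 0 (adjusted p at most 6e-06). For the peptide hormone genes, 2 of 22 tested members were higher and 8 were lower (3 and 8 adjusted over the list alone). Camera gave 3.6e-06 for a downward shift (range 4.7e-07 to adjusted p = 0.082 with an estimated correlation). Of the antigen presentation genes, 1 of 14 tested members was higher and 7 were lower (2 and 7 adjusted over the list alone). Camera gave 5.6e-05 for a downward shift (range 2.7e-07 to adjusted p = 0.31 with an estimated correlation). The immune marker Cd74 was at 0, 1 and 0 TPM in lower trachea NE against 255, 62 and 83 TPM in lung NE, and Tyrobp at 0 against 7, 28 and 25 TPM. Among the endothelial markers, 3 of 5 tested members were lower (3 adjusted over the list alone). Camera gave 0.0035 for a downward shift (range 0.00028 to adjusted p = 0.2 with an estimated correlation). On TPM as deposited limma called 6454 genes higher in lower trachea and 1556 lower, 80.6% higher. Under median-of-ratios scaling 2950 were higher and 2311 lower, 56.1% higher, and 2950 and 1485 were called under both.

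Upper trachea NE cells against lung NE cells gave Cxcl13 higher by 9.37 ± 0.72, adjusted p = 8.8e-08, Serpinb12 by 9.20 ± 0.38, adjusted p = 9.6e-11 and Snca, alpha-synuclein, at 525 ± 276 TPM against 4, 3 and 0 TPM. Gnat3 stood at 524 ± 151 TPM, Isl1 at 71.7 ± 9.29 TPM and Hepacam2 at 791 ± 302 TPM, each at 0 in lung NE cells (adjusted p at most 2.9e-07). Scn9a was higher by 4.29 ± 0.34, adjusted p = 8.8e-08, while Calca differed (-0.21 ± 0.39) and was not called (adjusted p = 0.9). For the tuft and taste cell genes, 10 of 17 tested members were higher (13 adjusted over the list alone). Camera gave 5.8e-05 for an upward shift (range 2.9e-07 to adjusted p = 0.32 with an estimated correlation). Resp18 was lower (-5.00 ± 0.56, adjusted p = 1.3e-05), Spp1 stood at 0, 17 and 0 TPM, and Rgs4, a regulator of G protein signalling, at 0 against 226 ± 139.8 TPM in lung. Of the peptide hormone genes, 1 of 22 tested members was higher and 7 were lower (2 and 7 adjusted over the list alone). Camera gave 2.3e-06 for a downward shift (range 3.1e-07 to adjusted p = 0.082 with an estimated correlation). Among the antigen presentation genes, 5 of 14 tested members were lower (7 adjusted over the list alone). Camera gave 6.7e-05 for a downward shift (range 4.4e-06 to adjusted p = 0.32 with an estimated correlation). Cd74 stood at 1, 98 and 0 TPM and Tyrobp at 0, 5 and 0 TPM in upper trachea NE, against the lung NE levels given above. With TPM as deposited limma called 4085 genes higher in upper trachea and 1392 lower, 74.6% higher. Under median-of-ratios scaling 2542 were higher and 1904 lower, 57.2% higher, and 2539 and 1357 were called under both. Without upper trachea NE 3 the count of 5477 was 7676, with 5026 genes shared.

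**Figure D4:**
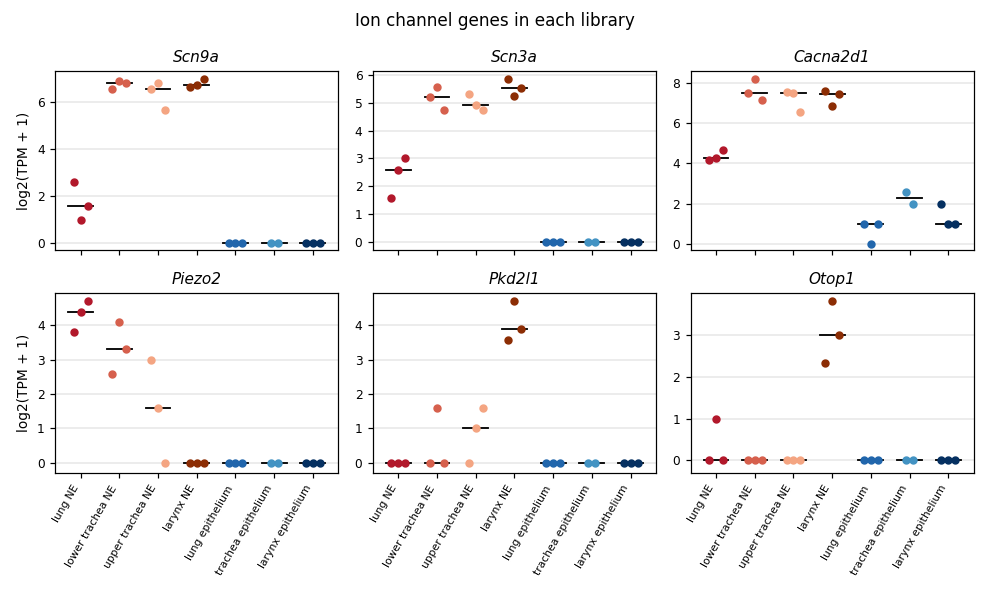
Levels of Scn9a, Scn3a, Cacna2d1, Piezo2, Pkd2l1 and Otop1 in log2(TPM + 1) for each library, with the 4 NE groups first and the 3 epithelia after them, points for libraries and a black line at the group median. Scn9a lies at 50 to 125 TPM in the NE cells of trachea and larynx and at 1 to 5 TPM in lung NE, and Piezo2 is listed at 0 in all larynx NE libraries.

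Between upper and lower trachea NE cells the number of called genes ranged with the setting from 0 to 422. The median gene was at -0.2, so the differences that limma tested lie below those printed here. Ascl1 differed by 0.12 ± 0.24, adjusted p = 0.95, Calca by 0.02 ± 0.39, adjusted p = 0.88, Scn9a (-0.19 ± 0.34, adjusted p = 0.61) and Chga (-0.80 ± 0.58, adjusted p = 0.57), none of them past the threshold. By limma on TPM as deposited, the calls were 7 genes higher and 3 lower in upper trachea; the 3 lower ones were Cd96, Snord35b and Zfp879, all listed at 0 in upper trachea NE and at 1 to 10 TPM in lower trachea NE. With median-of-ratios scaling limma called 0 genes, and hence 0 under both scalings, with 1070 at an unadjusted p under 0.05 against 1491 on TPM as deposited, while with array weights it called 422. Of the gland and goblet cell genes no single member was called, while the list shifted up by a median of 1.01. Camera gave 0.0016 for an upward shift (range 2.2e-05 to adjusted p = 0.29 with an estimated correlation, and 0.16 without lower trachea NE 3 and 0.053 without upper trachea NE 2). Of the muscle and cartilage genes no member was called over all genes and 5 of 9 were lower adjusted over the list alone, with a median of -1.57. Camera gave 0.0053 for a downward shift (range 1.1e-09 to 0.58, adjusted p = 0.44 with an estimated correlation, and 0.071 with no filter, 0.066 with only the groups compared fitted, 0.58 without lower trachea NE 2, 0.15 without lower trachea NE 3, 0.1 without upper trachea NE 1 and 0.099 without upper trachea NE 2). Acta2 was at 1, 157 and 52 TPM in lower trachea NE and 0 in upper trachea NE, and Tagln at 0, 74 and 24 TPM against 0, 1 and 0 TPM. The count of 10 was 60, 34 and 24 without lower trachea NE 1, 2 and 3, and 60, 73 and 23 without upper trachea NE 1, 2 and 3, the last sharing 9 genes with it.

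Larynx NE libraries against lower trachea NE libraries differed in transcripts of bitter taste receptors and acid-sensing channels. Taste cells among the sorted cells were not tested as a source of the acid-sensing transcripts, here or against upper trachea. The receptor Tas2r118 was at 176 ± 75.6 TPM against 0, 1 and 0 TPM (7.06 ± 0.78, adjusted p = 5.2e-05), and Tas2r105 and Tas2r104 were at 203 ± 75.3 TPM and 84.7 ± 19.1 TPM and listed at 0 in lower trachea NE cells (adjusted p at most 0.002); receptors of this family resemble each other, so how reads were split among them is uncertain. Car4, a carbonic anhydrase, was higher by 6.33 ± 0.54, adjusted p = 6.2e-06, Iapp by 5.77 ± 0.93, adjusted p = 0.0022 and Sptssb, of sphingolipid synthesis, by 4.97 ± 0.45, adjusted p = 9.2e-06. Of the acid-sensing genes 3 of 10 tested members were higher (3 adjusted over the list alone), with Otop1 at 8 ± 4.58 TPM against 0 (adjusted p = 1.9e-05) and Pkd2l1 at 16.7 ± 7.37 TPM against 0, 2 and 0 TPM (adjusted p = 9e-05, and 0.059 with only the groups compared fitted, range 1.4e-06 to 0.059). Camera gave 0.00024 for an upward shift (range 7.9e-06 to adjusted p = 0.12 with an estimated correlation). For the tuft and taste cell genes, 2 of 17 tested members were higher (8 adjusted over the list alone). Camera gave 7.7e-06 for an upward shift (range 1e-07 to adjusted p = 0.29 with an estimated correlation). Scgb1a1 was lower (-5.57 ± 0.96, adjusted p = 0.0034), and Piezo2 was at 0 against 10 ± 5.57 TPM (adjusted p = 0.0019).

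Keratins of squamous cells were also higher in larynx NE libraries. Of the squamous and hillock cell genes, 5 of 14 tested members were higher (8 adjusted over the list alone), with Krt6a at 32 ± 39.2 TPM against 2, 0 and 0 TPM. Camera gave 3.8e-11 for an upward shift (range 9.6e-14 to adjusted p = 0.037 with an estimated correlation). Among the basal cell genes, 3 of 8 tested members were higher (4 adjusted over the list alone), with Krt5 at 15 ± 4.36 TPM against 1.33 ± 0.580 TPM. Camera gave 4.9e-05 for an upward shift (range 1.2e-05 to adjusted p = 0.15 with an estimated correlation). These epithelial keratins were at 514 TPM or more for Krt6a and 265 ± 19.1 TPM for Krt5 in larynx epithelium. RNA carried over from larynx epithelium was not tested for squamous and basal genes, here or against upper trachea. With only the groups compared fitted Krt6a lost its call (0.21, range 0.00043 to 0.21), as did Krt5 with a pseudocount of 0.1 (0.12, range 0.00068 to 0.12). For the muscle and cartilage genes, 1 of 9 tested members was lower (5 adjusted over the list alone), with Acta2 and Tagln at 0 in larynx NE. Camera gave 9.3e-05 for a downward shift (range 4.3e-12 to adjusted p = 0.29 with an estimated correlation, and 0.067 without lower trachea NE 2). On TPM as deposited limma called 267 genes higher in larynx and 68 lower, 79.7% higher, and 202 and 25 were called under both scalings.

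Larynx NE cells against upper trachea NE cells again gave Car4 (6.06 ± 0.54, adjusted p = 7e-06), Iapp (5.01 ± 0.93, adjusted p = 0.0067), Sptssb (4.63 ± 0.45, adjusted p = 1.6e-05) and Ly6d (4.60 ± 0.65, adjusted p = 0.00051) as higher in larynx. Tas2r118 stood at 176 ± 75.6 TPM against 6.67 ± 6.66 TPM, Otop1 at 8 ± 4.58 TPM against 0 and Pkd2l1 at 16.7 ± 7.37 TPM against 0, 1 and 2 TPM (adjusted p at most 0.0023). Of the acid-sensing genes 2 of 10 tested members were higher (3 adjusted over the list alone). Camera gave 0.00042 for an upward shift (range 1.7e-05 to adjusted p = 0.12 with an estimated correlation). Of the basal cell genes, 3 of 8 tested members were higher (5 adjusted over the list alone), with Krt17 at 180 ± 214 TPM against 5 ± 4 TPM. Camera gave 6.3e-06 for an upward shift (range 4.9e-07 to adjusted p = 0.12 with an estimated correlation). Among the squamous and hillock cell genes, 2 of 14 tested members were higher (9 adjusted over the list alone). Camera gave 7.6e-08 for an upward shift (range 8.3e-11 to adjusted p = 0.082 with an estimated correlation). With TPM as deposited limma called 247 genes higher in larynx and 41 lower, 85.8% higher, and 158 and 27 were called under both scalings. All of these gene calls rest on the spread shared over the 7 groups: with only the groups compared fitted limma called 0 genes, with 1112 at an unadjusted p under 0.05. The call on Tas2r118 also ended with a pseudocount of 0.1 (adjusted p = 0.13, range 0.0012 to 0.13). The count of 288 was 441 without upper trachea NE 2, and 251 without upper trachea NE 3, with 198 shared.

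**Figure D5:**
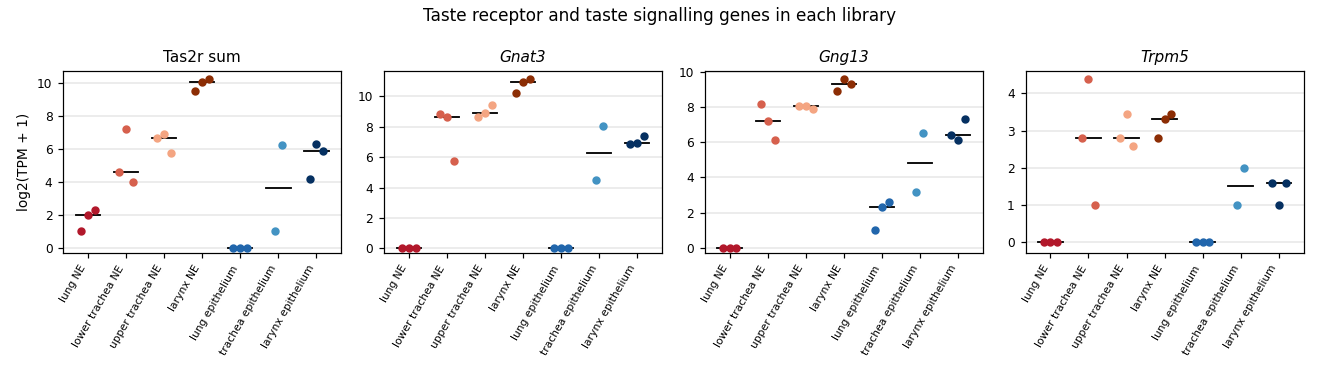
Summed TPM of the tested Tas2r bitter taste receptor genes, and Gnat3, Gng13 and Trpm5, in log2(TPM + 1) for each library, with the 4 NE groups first and the 3 epithelia after them, points for libraries and a black line at the group median. The Tas2r sum lies at 715 to 1192 TPM in larynx NE, at 15 to 144 TPM in the NE cells of the trachea and at 76 TPM or less in the epithelia.

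Larynx epithelium against lung epithelium compared the surroundings of the NE cells. Larynx epithelium held Sbpl at 8504 ± 387 TPM, Lipf at 8066 ± 3554 TPM and Dcpp3 at 45674 ± 16882 TPM, all listed at 0 in lung epithelium (adjusted p at most 1.4e-06). For the squamous and hillock cell genes, 11 of 14 tested members were higher (13 adjusted over the list alone), with Krt4 at 2869 ± 1113 TPM against 0, 1 and 0 TPM. Camera gave 8.1e-08 for an upward shift (range 2.8e-11 to adjusted p = 0.082 with an estimated correlation). Of the basal cell genes, 8 of 8 tested members were higher (8 adjusted over the list alone), with Krt5 higher by 6.23 ± 0.53, adjusted p = 9.2e-08 and Krt17 by 7.31 ± 0.69, adjusted p = 2.8e-07. Camera gave 1.1e-05 for an upward shift (range 1.5e-08 to adjusted p = 0.12 with an estimated correlation). Among the gland and goblet cell genes, 9 of 10 tested members were higher (10 adjusted over the list alone). Camera gave 3.4e-07 for an upward shift (range 4.1e-10 to adjusted p = 0.091 with an estimated correlation). For the immediate early and heat shock genes, 14 of 18 tested members were higher (18 adjusted over the list alone), with Fos higher by 4.08 ± 0.60, adjusted p = 1.3e-05 and Atf3 by 3.46 ± 0.51, adjusted p = 1.1e-05. Camera gave 2.5e-06 for an upward shift (range 3.3e-08 to adjusted p = 0.39 with an estimated correlation). Of the cell cycle genes, 12 of 16 tested members were higher (14 adjusted over the list alone). Camera gave 1e-05 for an upward shift (range 3.3e-07 to adjusted p = 0.29 with an estimated correlation).

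Lung epithelium was higher in alveolar type 2 cell transcripts. Sftpc was at 28089 ± 15067 TPM against 7, 0 and 2 TPM (-13.68 ± 0.89, adjusted p = 2.4e-08), and of the alveolar type 2 genes 5 of 10 tested members were lower (5 adjusted over the list alone) in larynx. Camera gave 1.7e-07 for a downward shift (range 1.4e-08 to adjusted p = 0.059 with an estimated correlation). Scgb1a1 was lower in larynx (-7.48 ± 0.96, adjusted p = 3.5e-05), while another club cell gene, the oxidase Cyp2f2, was higher by 5.46 ± 0.80, adjusted p = 1.9e-05. Slpi, a protease inhibitor of secretions, was lower (-5.97 ± 0.51, adjusted p = 7.2e-07), and Ifit3, an interferon-induced gene with a near-identical copy (-8.26 ± 0.72, adjusted p = 6.4e-07), at 0, 3 and 6 TPM against 608 ± 135 TPM. Cd74, which immune cells and alveolar type 2 cells make, was at 623, 385 and 490 TPM in lung epithelium and 5, 15 and 120 TPM in larynx epithelium, and the highest of 12 other immune markers was at 1, 8 and 0 TPM in lung epithelium. By limma on TPM as deposited, the calls were 7033 genes higher in larynx and 709 lower, 90.8% higher. Under median-of-ratios scaling 3510 were higher and 2427 lower, 59.1% higher, and 3369 and 709 were called under both, with 32 called in opposite directions.

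The last comparison asked whether the difference of NE cells from epithelium differed between larynx and lung. The difference of Chga was larger in larynx by 4.91 ± 0.82, adjusted p = 0.00095 (0.071 with a pseudocount of 0.1, range 1.3e-05 to 0.071), and those of Ascl1 and Scn9a, at the levels given above, and of Ddc, at 649.7 ± 22.5 TPM in larynx NE and 26 ± 16.5 TPM in lung NE, were larger too (limma adjusted p at most 0.00027). That of Cxcl13 was larger by 7.63 ± 1.01, adjusted p = 0.00013, and Gzma, a granzyme, by 7.93 ± 0.95, adjusted p = 4.7e-05, at 754 ± 191 TPM in larynx NE, 0, 7 and 0 TPM in lung NE and 13 TPM or less in the epithelia. Among the NE identity genes, 7 of 16 tested members were higher and 1 was lower (10 and 1 adjusted over the list alone) in larynx minus lung. Camera gave 9.7e-09 for an upward shift (range 9e-10 to adjusted p = 0.085 with an estimated correlation). For the sodium and calcium channel genes, 8 of 20 tested members were higher (11 adjusted over the list alone). Camera gave 1.9e-06 for an upward shift (range 3.2e-07 to adjusted p = 0.16 with an estimated correlation). Of the tuft and taste cell genes, 5 of 17 tested members were higher (8 adjusted over the list alone). Camera gave 2.3e-05 for an upward shift (range 1.9e-07 to adjusted p = 0.3 with an estimated correlation). Cartpt, Vgf and Piezo2 differed more in lung, where they stood at 417 ± 109 TPM, 36 ± 12 TPM and 19.3 ± 6.03 TPM in NE cells (adjusted p at most 0.00093). Among the squamous and hillock cell genes, 12 of 14 tested members were lower (13 adjusted over the list alone), with Sprr3 at 149 ± 22.3 TPM in larynx epithelium. Camera gave 4.8e-09 for a downward shift (range 2.3e-11 to adjusted p = 0.059 with an estimated correlation). On TPM as deposited limma called 1135 genes with a larynx minus lung value above 0 and 2093 with one below 0, 35.2% above 0, where either cell type of either tissue can set the sign. Under median-of-ratios scaling the numbers were 1604 and 1585, 50.3% above 0, and 912 and 1234 were called under both.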

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

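The tests on taste receptors and on splits of whole mice in this part were chosen after the results were seen, as was that on genes of high level. Those on the few genes that take much of the TPM and on the other splits of the samples were written before. No group held the 4 samples needed to test for a single library far from the rest.

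The contrast of NE cells with epithelium differed between larynx and lung beyond limma's threshold for these genes. The fitted difference, relative to the median gene, was 7.93 for Gzma, 7.68 for Slc38a11, a transporter at 219.7 ± 31.6 TPM in larynx NE and 0 in both lung groups, 7.63 for Cxcl13, 7.32 for Car4 at 378 ± 169 TPM in larynx NE, 6.74 for Snca and 6.61 for the chloride transporter Slc26a9. It was 7.45 for Agr3 and 6.89 for Calml4, which stood at 98 ± 81.7 TPM and 60 ± 34.8 TPM in lung epithelium and at 1 TPM or less in lung NE cells. It was -16.65, -15.33 and -12.67 for the near-identical Dcpp3, Dcpp2 and Dcpp1, -8.65 for Sbpl and -8.01 for Lipf, with means in larynx epithelium from 8066 TPM for Lipf to 45674 TPM for Dcpp3 and 0 in lung epithelium. It was -7.65 for Dmkn, -7.04 for Ly6g6c and -7.15 for Igf2, the last at 409.7 ± 193 TPM in lung NE and 0 in both larynx groups. Where a group was at 0 these sizes depend on the pseudocount.

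An entry named AAV2.CAG.tdT, which no comparison was set up to examine, reached 30444 TPM in a larynx epithelium library. It was kept among the tested genes, and was 1 of the 32 that hold 1% or more of any library. It stood at 17024 to 30444 TPM in the airway epithelium of mice 4 and 5 and at 1376 TPM in that of mouse 6, at 3883 to 12518 TPM in the airway NE cells of mice 4 and 5 and 285 to 1094 TPM in those of mouse 6, and at 958 to 1841 TPM in lung libraries of both cell types.

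Among genes called on TPM as deposited, 89.8, 85.9, 80.3 and 81.5% were higher in NE cells of lung, lower trachea, upper trachea and larynx. Under median-of-ratios scaling, which brings the median gene close to 0, the shares were 54.6, 47.3, 47.1 and 52.5%, a balance that this centring itself favours and that decides nothing. Low values lost at lower depth in epithelium would leave genes of high level balanced, and the tables argue against this as the whole cause: among 1668 to 2601 genes whose groups compared had a mean of 50 TPM or more, each group weighing the same, the lowest of the 4 shares was still 82.1% (79.9 to 83.1% with 1 library left out). A few genes that take most of the TPM in epithelium could account for part of the imbalance and stay open, since without 32 genes that hold 1% or more of any library the shares fell to 71.5, 65.7, 56.8 and 71.6%. A difference in total RNA or in the number of genes expressed between the cell types was not tested, since the deposited values carry no reference for amount.

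Bitter taste receptor transcripts were higher in larynx NE cells than in any other group, with sums of 715 to 1192 TPM against at most 144 TPM in every other library. RNA carried over from larynx epithelium would leave them at or below its level. The tables argue against it, with sums of 715 to 1192 TPM in larynx NE against 17 to 76 TPM in larynx epithelium. The median log2 difference of 34 Tas2r genes, larynx NE minus larynx epithelium, was 2.94 before the median gene is subtracted and 2.33 after. Its bootstrap SE of 0.28 was taken over genes, which share the same mice, and measures no spread between mice. Taste or tuft cells among the sorted cells stay open, since their list was shifted by 1.55, relative to the median gene, in larynx against lower trachea NE cells (camera adjusted p = 7.7e-06, range 1e-07 to adjusted p = 0.29 with an estimated correlation). The taste and tuft cell list holds neither Otop1 nor Pkd2l1, so it does not cover the acid-sensing channels. The biological difference that the design names, the airway level, stays open as well.

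Other splits of the 6 samples were refitted for the comparisons of 3 against 3 libraries, and 10 splits are too few for a share below 0.1. The real split called 9254 genes in lung NE cells against epithelium (highest other 8), 8034 in larynx (7), 7742 between the epithelia (11), and 7284, 8010 and 5477 for larynx, lower trachea and upper trachea against lung NE cells (8, 12 and 803). For larynx against lower and upper trachea NE cells it called 335 and 288 (11 and 29). In each of these only 1 split, the real one, called as many. Between upper and lower trachea 7 of 10 splits called as many as the real 10, with 34 as the highest other. Among splits that part all 3 same-mouse pairs, the highest other was 6 for lung, 7 for larynx, 11 between the tracheal levels, and 11 and 14 for larynx against lower and upper trachea. For the difference between larynx and lung in the contrast, 9 of 100 drawn exchanges of the tissue labels within each cell type, the real 3228 included, called as many. By the criterion written before, this share goes with chance. These exchanges, however, carry the tissue differences of each cell type into the contrast and part the cell types of a mouse. The criterion did not allow for this, so the exchanges decide nothing about chance either way. The highest other, 9990, exchanged all NE labels and kept the epithelium labels, and the second highest was 4678. With the mouse as a term and whole mice exchanged, 1 of 10 splits, the real one, called as many as its 3617 genes, and 10 splits are again too few for a share below 0.1. The highest other was 0 by limma, with 228 to 954 genes at an unadjusted p under 0.05.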

How the results depend on the processing

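Upper trachea NE 3 left out of every fit, copies of a symbol not summed and calls under both scalings were chosen after the data were examined. Of 325 results on named genes, 311 were called. Array weights, no filter, unsummed copies, the mouse as a block and each library left out in turn moved none of them across the threshold, while 17 lost the call with only the groups compared fitted, 5 with a pseudocount of 0.1 and 1 with quantile normalization. Of 384 list results, 12 gained and 24 lost the call with median-of-ratios scaling, 17 and 22 with quantile normalization, 17 and 12 with array weights, 11 and 13 with only the groups compared, 10 and 7 with no filter, 6 and 6 with a pseudocount of 0.1, and 2 and 3 with unsummed copies. Leaving upper trachea NE 3 out of every fit was run for the comparisons without that group, where it moved none of 266 gene results across the threshold, and of 256 list results 6 gained and 3 lost the call. Depth is unknown, and whole-number TPM limits genes near 1 TPM.

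Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested. In lung NE cells against epithelium 9254 became 5128 with quantile normalization, 5464 with median-of-ratios scaling and 3889 under both scalings. In lower trachea 8651 became 4170, 4024 and 3086 in the same order, and in larynx 8034 became 5107, 5139 and 4152. In upper trachea 6541 became 4146 with median-of-ratios scaling, 11319 with array weights, 3533 with only the groups compared and 3219 under both scalings. Against lung NE cells, larynx went from 7284 to 4768 under both scalings, lower trachea from 8010 to 5331 with quantile normalization, 5261 with median-of-ratios scaling and 4435 under both, and upper trachea from 5477 to 8551 with array weights and 2393 with only the groups compared. Between upper and lower trachea limma's 10 became 23 with a pseudocount of 0.1 and 422 with array weights. It became 0 with quantile normalization, with median-of-ratios scaling and with only the groups compared (1187, 1070 and 248 at an unadjusted p under 0.05), and hence 0 under both scalings. Larynx against lower trachea went from 335 to 213 with quantile normalization, 835 with array weights and 203 with only the groups compared. Larynx against upper trachea went from 288 to 154, 1349 and 0 in the same order (limma, 1112 at an unadjusted p under 0.05 for the last), and to 185 under both scalings. Larynx against lung epithelium went from 7742 to 4078 under both scalings, and the difference of contrasts from 3228 to 5504 with array weights and 2146 under both. The estimated correlation took the list calls from 140 to 12.

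With 1 library left out, counts ran from 5195 to 8077 in lower trachea, 4237 to 8818 in upper trachea, 23 to 73 between upper and lower trachea and 251 to 441 for larynx against upper trachea, with each library behind a larger change named in the report. The other counts stayed within 1.5 times of their value: 8040 to 8864 in lung, 6060 to 7396 in larynx, 5818 to 6483, 6045 to 7329 and 4210 to 7676 for larynx, lower and upper trachea against lung NE cells, 299 to 385 for larynx against lower trachea, 6523 to 7157 between the epithelia, 2460 to 3342 for the difference of contrasts and 135 to 145 for the lists. Over the fits without 1 library, list results gained the call 48 times and lost it 57 times. Results that turned were not called before. The immediate early and heat shock list between upper and lower trachea (camera adjusted p = 0.4, downward) went upward with array weights (0.02) and without upper trachea NE 3 (0.0021), with 0.57 as the highest over libraries left out and a range of 0.0021 to 0.91 over all alternatives. The pan-epithelial list between larynx and upper trachea (0.81, upward) went downward without upper trachea NE 3 (0.039), from 0.039 to 0.9 over libraries left out and to 0.99 over all alternatives.

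With the mouse as a block the counts were 9517, 9247, 6959 and 8236 for NE cells against epithelium in lung, lower trachea, upper trachea and larynx, and 148 lists were called. The replicate block ended the call on the NE identity list in larynx against lung NE cells (camera adjusted p = 0.045, 0.055 with the block, range 0.0067 to adjusted p = 0.53 with an estimated correlation). It brought 9 other lists under the threshold, from 0.05 to 0.13 without it to 0.035 to 0.049 with it, and changed no other call.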

Other observations

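All tests in this part were chosen after the values were seen. Interferon-stimulated genes, which cells switch on in response to interferon, were higher in lung NE cells than in NE cells of larynx and trachea, and higher in lung than in larynx epithelium. Of 32 genes listed, 26, 29 and 29 were lower in larynx, lower trachea and upper trachea NE cells than in lung NE cells, and 20 were lower in larynx than in lung epithelium, with none higher in any of these comparisons. The list's median, relative to the median gene, was -2.65, -2.85, -3.13 and -2.34 in the same order. Isg15 stood at 35.3 ± 14.5 TPM in lung NE and 3.33 ± 2.31 TPM in larynx NE (-3.58 ± 0.53, limma adjusted p = 0.00027), and at 73 ± 11.5 TPM and 7.67 ± 4.62 TPM in the epithelia (-3.84 ± 0.53, adjusted p = 0.00016). Oasl2, which responds to viral RNA, was at 49 ± 11.5 TPM and 5 ± 2 TPM in NE cells and 47 ± 7.21 TPM and 12.7 ± 1.15 TPM in the epithelia, and Rsad2 at 27.7 ± 6.03 TPM and 3.67 ± 1.15 TPM in NE cells.

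A hypothesis is that the lung libraries may hold an interferon response that larynx libraries of both cell types and tracheal NE libraries lack. The tables argue against scaling between tissues as the whole cause, since with median-of-ratios scaling the higher of the larynx minus lung medians in NE cells and epithelium was still -2.67. RNA of immune cells in the lung epithelium sorts is argued against by 12 immune markers other than Cd74, whose median was 0 TPM in every library and whose highest member stood at 1, 8 and 0 TPM, against 18 to 23.5 TPM for the interferon list. Cd74, which alveolar type 2 cells also make, was at 385 TPM or more there. In the lung NE sorts it stays open: the median was also 0, but the highest member reached 8, 28 and 25 TPM against 43.5, 34.5 and 26.5 TPM for the interferon list. The set of mice stays open and cannot be told apart from the tissue, because 0 mice gave cells of both. Infection, housing and date of the mice were not tested.

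The reporter entry PC.G5.tdT was at 189 to 2624 TPM in NE libraries and 7 to 30 TPM in epithelial ones, and the entry CRE.ERT2 at 0 to 3 TPM in lung NE, 3 to 51 TPM in the NE cells of trachea and larynx and 0 in every epithelial library.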
